A study of Mus musculus with 3 samples.

How the data were processed

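Each of the 3 libraries was read from its deposited matrix, which holds raw counts of unique molecular identifiers per gene and cell barcode. Per the file headers and the submitters' processing notes the counts came from Cell Ranger 6.1.2 and the mm10 mouse genome; the annotation release and the intron setting are not given in the sources used here. Per the labels the cells came from back skin digested with collagenase I and then trypsin. The matrices held 5621, 11144 and 11186 barcodes for control, 2-week knockout and 3-week knockout, over the same 32285 genes, with at least 500 UMIs per barcode. The deposited feature tables were used for gene symbols. No other unit was used, and no replicate was used because the series has 1 library per group.

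Cells with fewer than 500 genes (363, 960 and 754) or at least 15% mitochondrial counts (415, 973 and 954) were left out. Scrublet as built into scanpy was run on each library with its automatic threshold and left out 136, 312 and 443 doublets (2.71%, 3.16% and 4.43%). This kept 4886, 9557 and 9550 cells, or 86.9%, 85.8% and 85.4% of the barcodes. Ribosomal genes were 18.8%, 23.0% and 23.7% of the UMIs and mitochondrial genes 4.03%, 3.08% and 3.89%. The most abundant genes were Gm42418 in control (3.85%) and Malat1 in the knockouts (3.34% and 2.58%).

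The 3 libraries were clustered together, with no correction for library. Counts were scaled per cell and log transformed, 2000 variable genes were taken to 30 principal components, and a graph of 15 neighbours with Jaccard weights was partitioned by the Leiden algorithm at resolution 1 with seed 1, which gave 38 clusters. Clusters were named from marker genes written down before the data were examined, as the class with the highest mean standardised log2 CPM over its markers (offset 20 CPM). A name needed 3 markers found in at least 10% of the cells and a lead of 0.25 over the next class, and no other class with more markers among the 10 leading genes. Clusters with a cell cycle score of at least 1.5 were called cycling. Lineage followed keratin (3000 CPM), Vim (100 CPM) and Ptprc (100 CPM). The naming rule, its thresholds, the offset and the Jaccard weights were set after the clusters were seen: the lead of 0.25 was chosen because cluster 2, an upper hair follicle-like cluster, led by 0.27. The markers Krt85 and Ccl21a were not found by symbol. All class names are likenesses by markers.

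The basal class joined cluster 1, led by Epgn, Itga2, Tslp, Nrg1 and Ifi202b with Ptgs2, Igfbp3, Serpinb2, Itgb6 and Thbs1, and cluster 4, led by Fbxo32, Ndufa4l2, Krt14, Smoc2 and Tnfrsf19 with Wnt4. Suprabasal clusters were led by Krt1, Mt4 and Krt10, by Lor, Lce1m and Flg2, and by Krt77 and Sprr1b. The main bulge cluster was led by Krt24, Postn and Lgr5, and upper hair follicle clusters by Tm4sf1 and Gata6 or by Krt79 and Defb6. The dermal papilla or sheath cluster was led by Crabp1, Slc26a7 and Inhba. Fibroblast clusters were led by Col1a2 and Col1a1, by Cilp and Bgn, by Igfbp2, by Coch, Fmod and Tnmd, and by Apod and Cxcl1. The epithelial clusters without a class name (763, 1834 and 1479 cells) were kept in the epithelial share only. The cluster led by Gng11, Apold1 and Il6 showed both keratins and vimentin and was left unresolved (71, 1 and 1 cells).

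Within each class the counts of all cells of a library were summed and given as counts scaled to a common total (CPM). Ratios of CPM carry exact conditional 95% intervals, CPM values exact Poisson and shares exact Clopper-Pearson intervals. Log2 ratios used 5 CPM added to both sides. For the log2 ratios of Piezo1 the interval is that of the plain ratio. A gene was ranked in a class with at least 50 UMIs over the 2 libraries, at least 50 CPM in 1 of them and at least its level in the highest class divided by 5. Classes needed at least 100 cells per library, so macrophage-like cells were compared only between the 3-week knockout and control. A ratio against 0 counts was given as a bound from 3 counts. Named genes were those with the largest ratios among ranked genes other than ribosomal, mitochondrially encoded, haemoglobin and sex-linked check genes and unnamed gene models: 10 per side in basal-like cells and 3 per side in other classes, at least 2-fold. Not every gene that meets this rule is named in the text. A check of how many cells held each named gene, values within suprabasal and fibroblast clusters, the upper hair follicle and sebaceous shares without bulge cells, and Piezo1 within each basal cluster were added after the results were seen. Symbols of ribosomal pseudogenes and gene models were dropped after the first lists were seen, and upper hair follicle-like and dermal papilla-like cells were added to the gene lists then too.

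In total 32 gene lists were written before the data were examined, and each was placed among 10000 random lists of ranked genes matched by expression. Such a percentile describes these libraries and is not a test, because genes are not independent replicates. List members were called higher or lower at 1.5-fold. Gene list medians outside basal-like cells were computed with CPM scaling only. The 3' ends (last 300 bases) of the transcripts of named genes were searched with BLAST 2.17.0 against GENCODE vM21, which is on the mm10 assembly but may differ from the annotation behind the counts. Matches of at least 90 bases and 95% identity at another locus were counted as copies.

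The steps were first run on simulated counts. In 2519 and 2527 simulated basal genes, 100% of those set 2.5-fold and 4-fold apart and 0% of the unchanged and 1.5-fold ones passed the 2-fold rule. The intervals were checked in a part of the unchanged genes and held the true value in 96.0% and 94.4% of them. The simulated counts held counting error only, so this checks the steps and not the spread between mice. Alternatives were run for cell filters, doublets, Leiden resolution (0.5 and 2), separate clustering of each library, median-of-ratios scaling, leaving mitochondrial and ribosomal genes out of the total, thinning cells to 5000 UMIs, equal weight per cell, and leaving out cells with Mki67 or Top2a. Thinning left out 20, 78 and 66 basal-like, 67, 676 and 314 bulge-like and 74, 78 and 355 fibroblast-like cells. Intron counts, reads and the reporter allele were not analysed here. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.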

Results

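Transcripts of single cells from mouse back skin were compared between 3 libraries, 1 per group: a control, a Piezo1 knockout 2 weeks after tamoxifen and a Piezo1 knockout 3 weeks after tamoxifen. The control carried the K5-Cre-er driver and 1 floxed Piezo1 allele, and both knockouts carried the driver and 2 floxed alleles. Tamoxifen was given from postnatal day 48 to day 52. The control and the 2-week knockout were taken on day 62 and the 3-week knockout on day 71, with no control of that age. The 3-week knockout also differed in carrying 2 rather than 1 floxed Td allele. Every difference below is therefore a difference between 2 libraries that has no replicate check, and every interval is a 95% interval covering counting error only. After filtering, 4886 control, 9557 2-week and 9550 3-week knockout cells were kept, with median depths of 9978, 7498 and 8750 unique transcript counts (UMIs) per cell.

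Piezo1, the mechanically gated cation channel named in the labels, was lower in both knockout libraries in epithelial cells. It stood at 34.8, 27.7 and 15.2 CPM (UMIs of a class scaled to a common total) in the control, 2-week and 3-week libraries, from 1679, 2381 and 1444 UMIs. The ratios to control were 0.795 (0.747 to 0.847) at 2 weeks and 0.436 (0.406 to 0.468) at 3 weeks, pooled over classes whose shares differed between libraries: bulge-like cells, with the highest Piezo1 of the keratinocyte classes named here, were more common at 2 weeks. Bulge-like keratinocytes had ratios of 0.582 (0.513 to 0.661) and 0.288 (0.230 to 0.357), and interfollicular basal-like keratinocytes had 0.696 (0.601 to 0.805) and 0.464 (0.400 to 0.537). Upper hair follicle-like cells had 0.671 and 0.432, suprabasal-like cells 0.713 and 0.686, and cycling keratinocytes 0.639 and 0.463. Piezo1 was also lower outside the epithelium, where the driver is not expected to act: 62.6, 53.1 and 36.3 CPM in all other cells together, with ratios of 0.849 (0.743 to 0.968) and 0.580 (0.517 to 0.650). Dermal papilla-like cells had ratios of 0.561 (0.457 to 0.687) and 0.463 (0.378 to 0.567). Fibroblast-like cells had 0.900 (0.669 to 1.19) and 0.639 (0.529 to 0.771), and blood endothelial-like cells had 0.921 (0.646 to 1.31) and 0.685 (0.467 to 0.999). The labels do not give the floxed exons, and a tag at the 3' end of the transcript outside the deleted part would be counted from a recombined allele too, so these values neither check nor contradict the labels. The basal value depended on which cells were compared. Within the larger of the 2 basal clusters the ratios were 0.804 (0.687 to 0.939) and 0.513 (0.434 to 0.606). Within the smaller basal cluster alone they were 0.960 (0.577 to 1.67) and 0.926 (0.573 to 1.57), from 20 UMIs in control, so no difference was visible there. The class ratios lie below those of either cluster, so they partly follow the shares of the clusters, which differed between libraries.

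**Figure D1:**
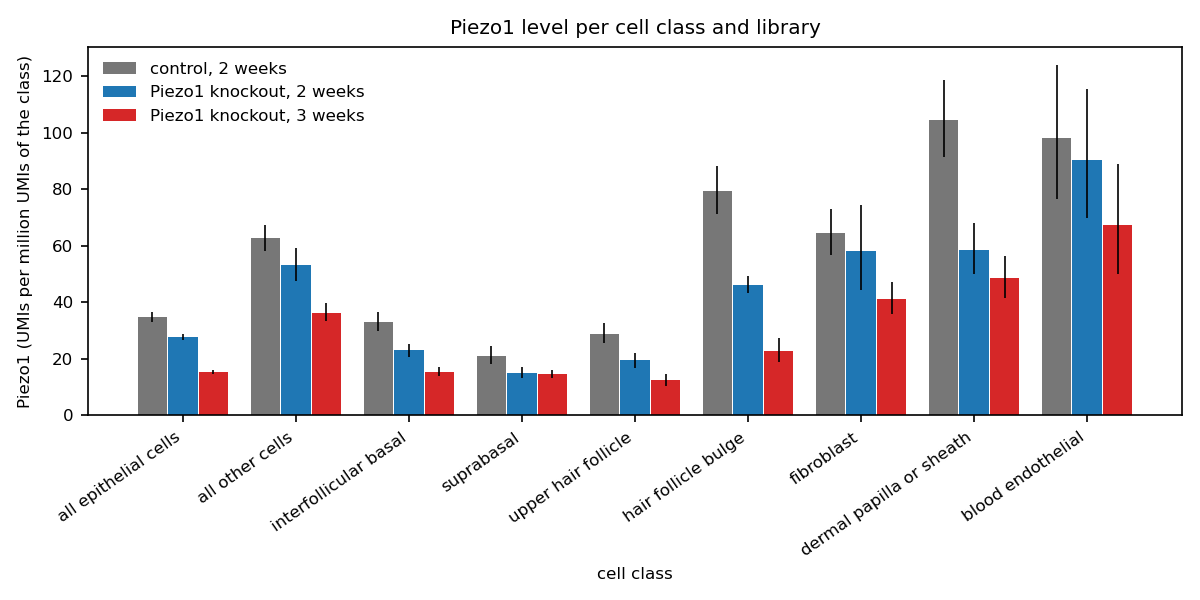
Piezo1 in CPM (vertical axis) by cell class (horizontal axis) in the 3 libraries, with 95% exact Poisson intervals as error bars. Piezo1 was lower in the knockout libraries in the bulge class (79.3, 46.1 and 22.8 CPM) and in the dermal papilla class (104, 58.5 and 48.4 CPM).

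The 2-week knockout library held a different mix of cells from the other 2. Epithelial cells were 67.1% (65.8 to 68.4) of the control, 88.4% (87.8 to 89.1) of the 2-week and 72.1% (71.2 to 73.0) of the 3-week knockout cells. Fibroblast-like cells were 8.90% (8.12 to 9.74), 1.76% (1.504 to 2.04) and 8.70% (8.14 to 9.28), and immune cells were 8.02% (7.28 to 8.82), 1.57% (1.33 to 1.84) and 5.83% (5.37 to 6.32). Macrophage-like cells numbered 108, 7 and 110, and T or natural killer-like cells 215, 100 and 287. Of epithelial cells, bulge-like cells were 16.1% (14.9 to 17.4), 35.5% (34.5 to 36.5) and 12.4% (11.6 to 13.2). Suprabasal-like cells were 8.29% (7.37 to 9.29), 7.91% (7.35 to 8.51) and 16.3% (15.5 to 17.2), and upper hair follicle-like cells were 21.9% (20.5 to 23.4), 13.1% (12.4 to 13.8) and 15.3% (14.5 to 16.2). Interfollicular basal-like cells were 22.2%, 17.2% and 26.9% of epithelial cells, and cycling keratinocytes were 5.18% (4.45 to 6.00), 4.37% (3.94 to 4.82) and 5.88% (5.34 to 6.47). Sebaceous gland-like cells were 2.99% (2.43 to 3.63), 0.248% (0.154 to 0.380) and 1.67% (1.38 to 2.00). Dermal papilla-like cells were 8.39%, 4.74% and 8.503% of all cells, while Schwann-like cells, at 79, 128 and 153, had a 2-week to control ratio of shares of 0.828 (0.621 to 1.11). These shares follow how the skin came apart as well as what it held, and epithelial cells were read to 12083, 7917 and 11056.5 UMIs in the median. Epithelial clusters without a class name held 23.3%, 21.7% and 21.5% of epithelial cells. The upper hair follicle share depended strongly on clustering and naming, with control values from 6.85% to 21.9%, but stayed lower at 2 weeks than in control in every alternative. Shares of epithelial cells add up, so a higher bulge share lowers the others. Among epithelial cells other than bulge it was higher at 2 weeks than in control at Leiden resolution 2 (14.1% against 12.8%). The same held with each library clustered on its own (8.67% against 8.17%), and it was lower in the other settings. The suprabasal share also depended on clustering: with each library clustered on its own it was 15.1%, 9.94% and 16.6%, so its difference between control and 3 weeks nearly vanished.

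**Figure D2:**
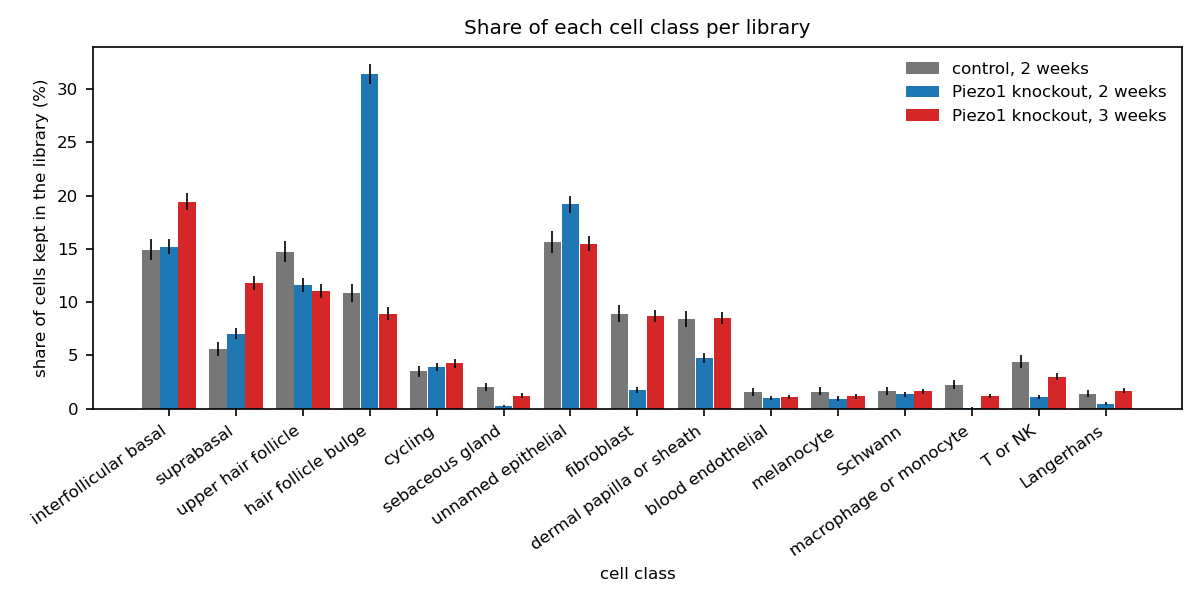
Share of the cells kept (vertical axis, percent) by cell class in the 3 libraries, with 95% Clopper-Pearson intervals as error bars. The bulge class was 10.8%, 31.4% and 8.92% of cells, and the fibroblast class 8.90%, 1.76% and 8.70%.

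In interfollicular basal-like keratinocytes the 2-week knockout library held less of the chemokine gene Ccl20, of Ccdc71l and of the oxysterol enzyme gene Ch25h than control. Fos, Socs3 and Irf1 were higher, in large part with the mix of 2 basal clusters described below, and the other leading higher genes were higher outside the epithelium as well. Fos stood at 1398 CPM in control and 3212 CPM in the 2-week knockout, 2.30-fold higher (2.26 to 2.34), and was also higher in fibroblast-like (log2 ratio 1.90) and dermal papilla-like cells (1.77). Socs3 was 2.13-fold higher (2.00 to 2.27) and Irf1 2.12-fold higher (1.97 to 2.29). Of genes of mitochondrial respiration, Atp5k was 2.26-fold (2.12 to 2.41) and Ndufa3 2.23-fold (2.02 to 2.46) higher, with log2 ratios of 1.13 and 0.82 in fibroblast-like and 0.86 and 0.55 in dermal papilla-like cells. Ndufb1-ps, a noncoding gene in the annotation used, was 2.22-fold higher (2.09 to 2.35), with 0.83 and 0.93 in those cells. Hmgn2 (2.65-fold, 2.28 to 3.08), Nmt1 (2.28-fold, 2.01 to 2.58), Plp2 (2.11-fold, 1.92 to 2.33) and Prxl2a (2.05-fold, 1.88 to 2.24) were also higher. Ccl20 was 4.01-fold lower (3.65 to 4.42), at 145 CPM in control and 36.2 CPM in the 2-week knockout, but it was found in only 10.8% and 6.54% of the cells and 1 control cell held 18.8% of its UMIs (118 CPM without that cell). Ccdc71l was 3.93-fold (3.58 to 4.31) and Ch25h 3.89-fold (3.42 to 4.43) lower. Phlda1 was 2.59-fold (2.52 to 2.65), the amino acid transporter gene Slc6a14 2.46-fold (2.26 to 2.69), the tissue factor gene F3 2.35-fold (2.27 to 2.43) and Gadd45a 2.33-fold (2.22 to 2.45) lower. Itga2 (2.79-fold, 2.66 to 2.93), Ifi202b (2.65-fold, 2.61 to 2.69) and Thbs1 (2.55-fold, 2.51 to 2.60) were lower too. In all, 14 of 2496 ranked genes were at least 2-fold higher and 28 at least 2-fold lower. With the 2 basal clusters weighed equally these counts were 3 and 9, and within the smaller cluster alone 5 and 4.

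The larger basal cluster held 584 of 729 basal-like cells in control, 839 of 1452 in the 2-week and 945 of 1852 in the 3-week knockout, so each class value mixes 2 cell states in different shares. All 10 of the lower genes named above mark the larger cluster: its log2 ratio to the smaller was 4.01 for F3, 3.21 for Phlda1, 2.88 for Slc6a14, 2.80 for Ifi202b, 2.78 for Gadd45a and 2.34 for both Ccdc71l and Itga2. Fos (−2.06), Socs3 (−2.84) and Irf1 (−1.89) mark the smaller cluster. Within the larger cluster Ccl20 was 3.60-fold, Ccdc71l 3.21-fold, Ch25h 3.55-fold and Phlda1 2.08-fold lower at 2 weeks than in control, and Hmgn2 was 2.81-fold and Atp5k 2.17-fold higher. Fos was 1.66-fold and Socs3 only 1.23-fold higher there, and with both clusters weighed equally their log2 ratios were 0.45 and 0.22. Irf1 was 1.42-fold higher in the larger and 1.47-fold in the smaller cluster. Within the smaller cluster Ccl20 was 2.27-fold lower, while Ch25h, Phlda1 and F3 lay on the other side, with log2 ratios of 0.63, 0.20 and 0.49. The smaller cluster held 145 control cells and no interval was computed for these values, so they carry no counting check. The 3' ends of Hmgn2, Plp2 and Atp5k closely match 14, 2 and 1 other loci of the mouse genome, so the values of these 3 genes are uncertain.

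Among gene lists in basal-like cells, the medians placed lowest among random lists at 2 weeks were those of interferon response, mitochondrially encoded, actin or myosin, p53 target, NF-kB target and MHC class I genes, though few or no members passed 1.5-fold in several of them. Of 4 ranked interferon response genes 0 were at least 1.5-fold higher, 3 lower and 1 between, with Bst2 2.35-fold and Ifi27l2a 1.92-fold lower (median log2 ratio −0.90, percentile 0.01 of matched random lists). The 12 mitochondrially encoded genes had 3 higher, 1 lower and 8 between (−0.34, percentile 0.10). Of 8 NF-kB targets 0 were higher, 3 lower and 5 between, with Tslp 1.64-fold and Ptgs2 1.62-fold lower beside Ccl20 (−0.46, percentile 0.42); Tslp and Ptgs2 are among the leading genes of the larger cluster. Of 8 p53 targets 0 were higher, 2 lower and 6 between, with Sesn2 1.53-fold and Cdkn1a 1.44-fold lower (−0.41, percentile 0.39). All 8 MHC class I genes lay between, with Psmb8 1.48-fold and Tap1 1.44-fold lower (−0.34, percentile 0.68). Of 13 actin or myosin genes 0 were higher, 3 lower and 10 between, with Zyx 2.17-fold, Actb 1.95-fold and Myh9 1.69-fold lower (−0.38, percentile 0.33), but the median was 0.11 within the smaller cluster. Hemidesmosome genes had 0 higher, 2 lower and 9 between (−0.23, percentile 4.93). The 3 ranked YAP targets had 0 higher, 1 lower and 2 between (−0.32, percentile 14.8).

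The medians placed highest in basal-like cells were those of ribosomal protein, immediate early, oxidative phosphorylation, glycolysis, metallothionein or redox and Wnt genes, again with few members past 1.5-fold. Of 14 immediate early genes 4 were higher, 0 lower and 10 between, with Fosb 1.66-fold and Atf3 1.62-fold higher beside Fos and Socs3 (0.28, percentile 99.8), but the median was −0.041 within the larger cluster. Of 8 glycolysis or hypoxia genes 2 were higher, 1 lower and 5 between, with Bnip3 1.74-fold and Tpi1 1.57-fold higher and Ndrg1 1.61-fold lower (0.23, percentile 99). All 12 oxidative phosphorylation genes lay between, with Cox7c 1.42-fold and Cox6c 1.29-fold higher (0.24, percentile 99.7). Of 4 Wnt genes 1 was higher and 3 between (0.23, percentile 97.0); that 1, Wnt4, is among the leading genes of the smaller cluster. Ribosomal protein genes had 13 higher, 0 lower and 70 between (0.16, percentile 100). Of 3 metallothionein or redox genes 1 was higher, 1 lower and 1 between, with Mt1 1.64-fold higher and Txnrd1 1.71-fold lower (0.58, percentile 97.7). Desmosome genes had 0 higher, 2 lower and 13 between (−0.08, percentile 27.7), but a median of 0.079 within the smaller cluster, and the 3 circadian genes had 1 higher, 0 lower and 2 between (0.03, percentile 51.9). All 7 heat shock genes (0.06, percentile 66.7), all 10 calcium handling genes (0.02, percentile 70.3) and all 3 BMP or TGF-beta genes (−0.18, percentile 35.5) lay between. Cell cycle and anagen lists had 1 ranked member each in basal-like cells.

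In suprabasal-like cells the 2-week knockout library held more Hes1 and Irf1 and less Ccdc71l and Ifi202b than control, and of the cornified envelope genes it held less Flg and Lce1h. Hes1, a Notch target, was 4.27-fold higher (3.65 to 5.02) and also higher in fibroblast-like (log2 ratio 1.60) and dermal papilla-like cells (1.78). Irf1 was 2.95-fold higher (2.66 to 3.28), and Churc1 3.42-fold (2.92 to 4.02), the latter with 122 close matches to its 3' end. Ccdc71l was 3.75-fold (3.45 to 4.09), Ifi202b 3.42-fold (3.34 to 3.52) and Lce1h 3.84-fold (3.36 to 4.40) lower, Lce1h resting on only 11 and 17 cells. Of 20 ranked spinous or cornified genes 0 were higher, 4 lower and 16 between, with Flg 3.20-fold and Cdsn 1.67-fold lower (−0.18, percentile 1.95). Flg is a leading gene of 1 of the 3 suprabasal clusters, which held 35 of 272 control and 85 of 669 2-week knockout cells, and within it Flg stood at 1376 CPM in control, 528 at 2 weeks and 866 at 3 weeks. The suprabasal class markers had a median log2 ratio of 0.14. Of 4 wound keratin genes 0 were higher, 2 lower and 2 between (−0.57, percentile 0.89), and the 3 fatty acid genes (−0.02) and 9 cholesterol synthesis genes (−0.01) all lay between. In total 9 genes were at least 2-fold higher and 29 lower.

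In bulge-like cells Hes1 was 2.93-fold (2.68 to 3.21), the clock output gene Dbp 2.61-fold (2.26 to 3.03) and Lsmem1 2.67-fold (2.13 to 3.38) higher at 2 weeks. Thbs1 was 2.92-fold (2.86 to 2.99) and Flrt3 2.51-fold (2.35 to 2.69) lower, Thbs1 also in fibroblast-like (log2 ratio −0.99) and dermal papilla-like cells (−0.88). Dbp was higher outside the epithelium as well, with log2 ratios of 1.64 in fibroblast-like and 2.14 in dermal papilla-like cells. Of 11 hair follicle stem cell genes 1 was higher and 10 between, with Fgf18 1.67-fold and Tbx1 1.44-fold higher (0.15, percentile 92.1), and of 3 glucocorticoid response genes 0 were higher, 2 lower and 1 between (−0.66, percentile 0.85). In upper hair follicle-like cells 12 of 14 immediate early genes were higher and 0 lower, with Fos 4.56-fold, Atf3 3.18-fold and Socs3 2.85-fold higher (1.10, percentile 100). The immediate early median was 0.06 in bulge-like cells, 0.67 in dermal papilla-like and 1.17 in fibroblast-like cells. Counts at least 2-fold higher and lower were 12 and 20 in bulge-like and 26 and 16 in upper hair follicle-like cells. Class markers of the upper hair follicle had a median log2 ratio of −0.39 to control, with single markers from −2.76 to 0.67. The largest cluster of that class held 445 of 719 control and 757 of 1108 2-week knockout cells. Values within its clusters were not computed, so the upper hair follicle values, those of immediate early genes included, may partly follow the mix of clusters.

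Fibroblast-like cells of the 2-week knockout held less of the fibrillar matrix genes and dermal papilla-like cells more of the clock genes than control. Of 14 fibrillar matrix genes 0 were higher, 12 lower and 2 between, with Fbn1 2.93-fold, Lox 2.49-fold, Col1a1 2.36-fold and Eln 2.35-fold lower (−0.95, percentile 0). The markers of the fibroblast class itself had nearly the same median (−0.93). Most of them (Col1a1, Col1a2, Col3a1, Dcn, Lum and Sparc) are also in the matrix list, so this cannot tell matrix genes from class markers. Of 8 matrix remodelling genes 0 were higher, 3 lower and 5 between (−0.39, percentile 2.75). Tslp had 10 UMIs in control and 106 UMIs at 2 weeks in fibroblast-like cells, but 1 cell held 86.8% of the latter, so no ratio is given. Cd24a was 8.39-fold higher (5.57 to 12.9), from 35 and 79 UMIs. Keratin transcripts from other cells were also more abundant there, with Krt14 at 125 and 840 CPM and Krt5 at 93.2 and 588 CPM, so the Cd24a value is uncertain. Ifi205 was 11.2-fold (6.92 to 19.3) and Ptx3 18.3-fold (6.17 to 89.4) lower in the class, the latter from 204 and 3 UMIs, but within the cluster led by Col1a2 and Col1a1 Ifi205 stood at 251 and 65.2 CPM, and the end of Ifi205 matches 1 other locus. Mup16 met the naming rule, but all 348 of its UMIs in control came from 1 cell. In dermal papilla-like cells 4 of 5 circadian genes were higher and 1 between, with Nr1d1 2.32-fold, Tef 2.30-fold and Per1 2.29-fold higher and Arntl 1.48-fold lower (1.04, percentile 100), beside a median of −0.11 for all ranked genes. The fibroblast comparison mixes different cells. The cluster led by Col1a2 and Col1a1 held 287 of 435 control but 41 of 168 2-week knockout cells, and the cluster led by Coch and Fmod held 20 and 52. Fmod (6.18-fold higher) lay almost wholly in the latter, at 2156 and 1679 CPM there. Within the former Col1a1 stood at 28383 and 17635 CPM and Fbn1 at 1565 and 770 CPM, a smaller difference than in the class. In the cluster led by Igfbp2 it was nearly absent for Col1a1 (20092 and 19317 CPM) and smaller than in the class for Fbn1 (948 and 856 CPM) and Eln (626 and 347 CPM). Lox went the other way there (56.5 and 114 CPM, from 38 and 24 UMIs). In the cluster led by Cilp and Bgn it was as large as in the class, with Col1a1 at 5074 and 2116 CPM and Fbn1 at 406 and 162 CPM.

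**Figure D3:**
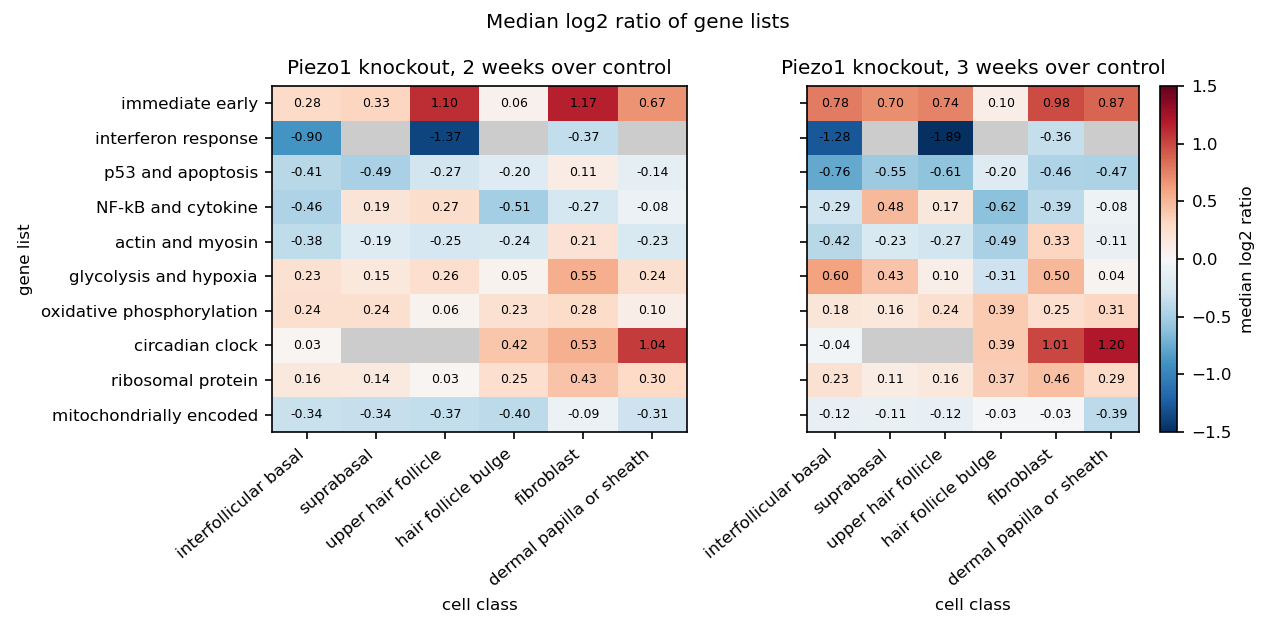
Median log2 ratio to control of 10 gene lists (rows) in 6 cell classes (columns) for the 2-week and 3-week knockout libraries; grey marks fewer than 3 ranked members, and the lists shown were chosen after their values were seen. Immediate early genes were higher in upper hair follicle-like cells at 2 weeks (1.10), and interferon response genes lower in basal-like cells (−0.90).

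Between the 2 knockout libraries, 3 weeks against 2 weeks, basal-like cells differed by few genes: 3 of 2433 ranked genes were at least 2-fold higher and 7 lower. Ccl20 was 2.88-fold (2.63 to 3.15), Zbtb16 2.24-fold (2.02 to 2.49) and the glycolytic gene Eno1 2.02-fold (1.85 to 2.20) higher at 3 weeks. Lower were Mmp3 (2.46-fold, 2.21 to 2.73), Ifi27l2a (2.27-fold, 2.17 to 2.38), Hs3st1 (2.13-fold, 1.94 to 2.35), F3 (2.05-fold, 1.97 to 2.13) and Tmcc3 (2.04-fold, 1.92 to 2.17). Some of these differed the same way outside the epithelium: in dermal papilla-like cells the log2 ratios were 0.89 for Zbtb16, 0.89 for Eno1, −2.22 for Mmp3 and −1.36 for Ifi27l2a. Wdr89 was 5.52-fold lower (5.26 to 5.80), and was lower in every epithelial and dermal papilla-like class compared. The 3' ends of Wdr89 and Eno1, with 19 and 5 close matches elsewhere, leave these values uncertain. Of 14 immediate early genes 4 were higher and 10 between, with Btg2 1.82-fold and Ier2 1.60-fold higher (0.47, percentile 100), while the median was −0.42 in upper hair follicle-like cells. Of 8 NF-kB targets 1 was higher, 1 lower and 6 between (0.25, percentile 99.9), with Ccl20 and Nfkbia (1.44-fold) higher and Il33 1.58-fold lower. Of 9 glycolysis genes 1 was higher and 8 between, with Gapdh 1.40-fold higher (0.25, percentile 100), and p53 targets had 0 higher, 1 lower and 7 between (−0.23, percentile 6.62). Of 14 desmosome genes 0 were higher, 1 lower and 13 between (−0.18, percentile 3.77), and of 12 mitochondrially encoded genes 1 was higher, 1 lower and 10 between (0.29, percentile 100). With mitochondrial and ribosomal genes left out of the total, 7 of the 3279 genes then ranked were at least 2-fold higher and 7 lower. Hs3st1 had a log2 ratio of 0.38 within the smaller basal cluster.

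In suprabasal-like cells 5 of 20 spinous or cornified genes were higher at 3 weeks than at 2 weeks, 0 lower and 15 between (0.20, percentile 100). Flg was 2.37-fold (2.26 to 2.48), Lce1h 2.95-fold (2.62 to 3.34) and the acute phase gene Orm1 2.32-fold (2.23 to 2.42) higher. Bloc1s1 was 2.19-fold lower (1.99 to 2.42). The suprabasal cluster led by Lor and Flg held 85 of 669 cells at 2 weeks and 281 of 1125 at 3 weeks, and within it Flg was at 528 and 866 CPM, Lce1h at 78.8 and 159 CPM and Orm1 at 499 and 825 CPM. In bulge-like cells Tsc22d3, a glucocorticoid-induced gene, was 2.88-fold higher (2.57 to 3.23), and Krt16 (5.04-fold, 4.32 to 5.93) and Ftl1-ps1 (3.74-fold, 3.06 to 4.62) were lower. Krt16 was found in 14.8% of these cells at 2 weeks and 9.04% at 3 weeks. Ftl1-ps1 was lower by a like amount outside the epithelium, with log2 ratios of −1.75 in fibroblast-like and −1.81 in dermal papilla-like cells, beside −1.68 in bulge-like cells. The largest bulge cluster held 2308 of 3000 cells at 2 weeks and 594 of 852 at 3 weeks, and values within it were not computed. Of 4 glucocorticoid response genes in bulge-like cells 2 were higher, 1 lower and 1 between (0.64, percentile 100), and of 11 hair follicle stem cell genes 0 were higher, 2 lower and 9 between (−0.04). In fibroblast-like cells Gpx3 (5.53-fold, 3.91 to 8.09), Cyp2f2 (5.05-fold, 4.08 to 6.33) and Ccn5 (5.55-fold, 3.05 to 11.2) were higher. The cluster led by Col1a2 and Col1a1 held 41 of 168 cells at 2 weeks and 522 of 831 at 3 weeks, and within it Cyp2f2 stood at 220 and 574 CPM and Gpx3 at 65.2 and 257 CPM. Fibrillar matrix genes had 5 higher, 0 lower and 9 between (0.14, percentile 94.9) in the class, and within that cluster they went both ways: Col1a1 (17635 and 9642 CPM) and Col1a2 (20904 and 16648 CPM) were lower at 3 weeks, and Fbn1 (770 and 1067 CPM) and Eln (346 and 596 CPM) were higher. Kera (60.4-fold), Fmod (28.8-fold) and Coch (16.9-fold) were lower, but these are leading or nearly exclusive genes of the cluster led by Coch and Fmod, which held 52 of 168 and 8 of 831 cells. Within it Fmod stood at 1679 and 2144 CPM, Coch at 4790 and 6601 CPM and Kera at 241 and 197 CPM. Single copies elsewhere match the ends of Bloc1s1 and Orm1, and 16 match that of Ftl1-ps1.

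Against control, 22 genes in basal-like cells were at least 2-fold lower in both knockout libraries and 5 were higher in both. Among the 2405 nameable genes ranked in both comparisons, independent lists of the sizes found there (28 and 93 lower, 11 and 12 higher) would share 1.08 and 0.05 genes, and 100 simulated draws of unchanged knockouts against the same control gave 0. Those draws hold counting error only, under which almost no gene passes the 2-fold rule, so they do not measure what 1 control mouse shared by both comparisons adds; part of the excess may come from it. F3 was 2.35-fold lower at 2 weeks and 4.80-fold (4.63 to 4.99) at 3 weeks, and Slc6a14 was 2.46-fold and 4.32-fold (3.94 to 4.75) lower. Phlda1 was 2.59-fold and 3.62-fold (3.52 to 3.71), Ccdc71l 3.93-fold and 3.78-fold (3.49 to 4.10), Gadd45a 2.33-fold and 2.74-fold (2.62 to 2.87) and Plet1 2.26-fold and 2.77-fold (2.71 to 2.83) lower. Plet1 is also among the markers used to name upper hair follicle-like cells. Its log2 ratios at 2 and 3 weeks were −0.92 and −1.11 within the larger basal cluster and −0.15 and −0.20 within the smaller. The other genes lower in both included Ch25h, Areg, Epha4, Bst2, Rassf9, Nedd4l, Clic4, Ppif, Ell2 and Nipal1. Itga2 (2.79-fold and 5.37-fold), Ifi202b (2.65-fold and 4.23-fold), Itgb6 (2.30-fold and 2.70-fold) and Serpinb2 were among them too, and most of these genes mark the larger basal cluster. Fos was higher in both (2.30-fold and 2.94-fold), but with the clusters weighed equally its log2 ratios were 0.45 and 0.57. It was 1.66-fold and 3.07-fold higher within the larger cluster and 1.33-fold and 1.26-fold within the smaller, so at 3 weeks the larger cluster kept the difference. In the 3-week knockout 11 of 14 immediate early genes were higher than in control and 0 lower (0.78, percentile 100), 5 of 9 glycolysis genes higher and 1 lower (0.60, percentile 100), and 4 of 7 p53 targets lower and 0 higher (−0.76, percentile 0.10). Of 4 interferon response genes 0 were higher and 3 lower (−1.28, percentile 0.18). These list values are those of the class, so they may partly follow the different mix of the 2 basal clusters. At 3 weeks the immediate early gene Socs3 had log2 ratios of 0.93 in the larger and 0.083 in the smaller cluster. The p53 target Gadd45a had −0.98 and 0.024, while the interferon response gene Bst2 was lower in both (−1.56 and −2.11). At 3 weeks 20 of 2491 genes were at least 2-fold higher than in control and 93 lower. These counts were 33 and 59 with median-of-ratios scaling. They were 43 and 77, of 3294 genes then ranked, with mitochondrial and ribosomal genes left out of the total. In the main analysis the median log2 ratio of all ranked genes was −0.13 (−0.14 in bulge-like and in upper hair follicle-like cells). With the basal clusters weighed equally the counts were 5 and 29, and within the smaller cluster alone 12 and 23. Within the smaller basal cluster 9 of the 22 genes lay above control at 3 weeks, among them Ch25h, Areg, Rassf9 and Slc6a14, with log2 ratios of 0.82, 0.45, 0.33 and 0.33, and Gadd45a and Itgb6, with 0.024 and 0.012. The values of Gadd45a and Itgb6 are near 0. That cluster held 145 control cells and no interval was computed for gene values within it, so these signs carry no counting check.

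**Figure D4:**
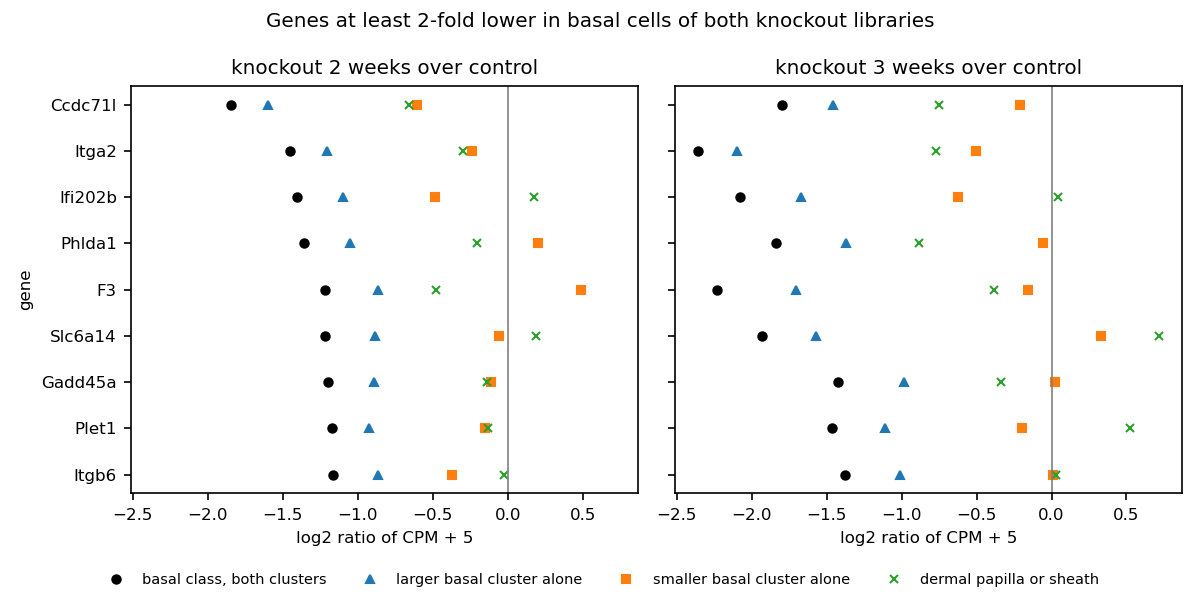
Log2 ratio to control (horizontal axis) of the 9 genes with the largest ratios among the 22 lower in both knockout libraries (vertical axis), in the basal class, in each of its 2 clusters and in dermal papilla-like cells, for 2 weeks and 3 weeks. Over all 22 genes the median of the mean log2 ratios was −1.31 in the class, −1.06 in the larger cluster and −0.04 in the smaller cluster.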

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

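No paired analysis was possible because each group had 1 library. The alternatives for filters, doublets, clustering, scaling and depth were chosen before the data were examined. Chosen after the result was seen were the analyses of the 2 basal clusters, the naming margin of 0.3, and the use of any alternative for the bulge, suprabasal and upper hair follicle shares of epithelial cells. Shares and gene counts are given as control, 2-week and 3-week knockout unless a library is named. The cause of a difference was not tested except where stated.

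Cell shares moved most for upper hair follicle-like cells. At Leiden resolution 0.5 the fibroblast share was 7.20%, 1.22% and 6.66%, the suprabasal share of epithelial cells 14.1%, 12.5% and 22.9%, and the upper hair follicle share 8.26%, 4.03% and 7.03%. At resolution 2 the epithelial share of control was 68.6%, the bulge share 36.6% at 2 weeks and 13.4% at 3 weeks, the suprabasal share 6.26% at 2 weeks and 14.5% at 3 weeks, and the upper hair follicle share 10.7%, 8.92% and 10.6%. With at least 1000 genes and under 10% mitochondrial counts the epithelial share was 69.1%, 89.3% and 73.2%, the bulge share 19.7%, 41.7% and 13.9%, the upper hair follicle share 10.2%, 7.13% and 9.02%, and the suprabasal share at 2 weeks 7.09%. With doublets kept the bulge share was 20.1%, 40.7% and 14.6%, the suprabasal share 6.78%, 6.28% and 14.8%, and the upper hair follicle share 11.4%, 7.26% and 9.86%. In that setting the 3-week epithelial share was 70.3% and the 3-week immune share 6.37%. With each library clustered on its own the epithelial share of control was 64.0%, the suprabasal share 15.1%, 9.94% and 16.6%, the bulge share 15.7% at 3 weeks, and the upper hair follicle share 6.85%, 5.59% and 8.26%. Without a cell filter the bulge share was 14.2%, 30.4% and 11.2%, the suprabasal share 13.9%, 10.3% and 22.7%, and the upper hair follicle share 7.64%, 4.84% and 7.67%. With a naming margin of 0.3 cluster 2 lost its name by construction, and the upper hair follicle share was 8.35%, 4.15% and 7.05%. In every setting the bulge share was highest and the fibroblast and immune shares lowest at 2 weeks. The upper hair follicle share of all epithelial cells was lower at 2 weeks than in control in every setting, but not once bulge cells were left out.

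Numbers of genes at least 2-fold apart in basal-like cells were as follows. At 2 weeks against control 14 were higher in the main analysis, 9 with doublets kept and 9 with cells thinned to 5000 UMIs. With median-of-ratios scaling 33 were higher and 59 lower at 3 weeks against control. With mitochondrial and ribosomal genes out of the total the higher counts were 22 at 2 weeks against control, 7 at 3 weeks against 2 weeks and 43 at 3 weeks against control. More genes passed the 50 CPM minimum there (3265, 3279 and 3294 ranked). A minimum of 20 or 200 UMIs and a pseudocount of 1 CPM cannot move these counts, because the 50 CPM minimum decides and the counts use plain ratios. Without cells holding Mki67 or Top2a the counts were 13 higher and 31 lower at 2 weeks against control.

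The log2 ratio of Piezo1 moved with the setting and lay near 0 in the smaller basal cluster. In basal-like cells at 3 weeks against control it was −0.80 with median-of-ratios scaling, −0.86 with mitochondrial and ribosomal genes out of the total, and −0.86 at Leiden resolution 2. In bulge-like cells it was −1.47 at 3 weeks against control with median-of-ratios scaling, and −0.65 at 3 weeks against 2 weeks when each cell weighed the same. The ranges of the log2 ratio over all settings were −0.84 to −0.63, −0.99 to −0.65 and −1.75 to −1.47 in bulge-like cells for 2 weeks against control, 3 weeks against 2 weeks and 3 weeks against control.

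With both basal clusters weighed equally, 3 genes were higher and 9 lower at 2 weeks against control, 4 lower at 3 weeks against 2 weeks, and 5 higher and 29 lower at 3 weeks against control. The log2 ratio of Piezo1 was then −0.20 at 2 weeks against control, −0.35 at 3 weeks against 2 weeks and −0.56 at 3 weeks against control. The NF-kB median at 3 weeks against control turned from −0.29 to 0.019. In the largest basal cluster alone 5 genes were higher and 18 lower at 2 weeks against control, 5 higher at 3 weeks against 2 weeks, and 8 higher at 3 weeks against control. Piezo1 was −0.27 and −0.81 there at 2 and 3 weeks against control, and the immediate early median at 2 weeks turned from 0.28 to −0.041.

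In the smaller basal cluster alone 5 genes were higher and 4 lower at 2 weeks against control, 4 lower at 3 weeks against 2 weeks, and 12 higher and 23 lower at 3 weeks against control. Piezo1 was −0.041 at 2 weeks against control, −0.036 at 3 weeks against 2 weeks and −0.077 at 3 weeks against control, no visible difference. At 2 weeks against control the desmosome median turned from −0.080 to 0.079 and the actin or myosin median from −0.38 to 0.11. At 3 weeks against control the heat shock median turned from 0.090 to −0.051, NF-kB from −0.29 to 0.20 and actin or myosin from −0.42 to 0.15, and at 3 weeks against 2 weeks MHC class I from 0.079 to −0.065. Ch25h turned from −1.72 to 0.63, Phlda1 from −1.36 to 0.20 and F3 from −1.22 to 0.49 at 2 weeks against control. Hs3st1 turned from −0.98 to 0.38 at 3 weeks against 2 weeks. At 3 weeks against control Slc6a14 turned from −1.93 to 0.33, Gadd45a from −1.42 to 0.024 and Itgb6 from −1.38 to 0.012. No interval was computed for these gene values within the smaller cluster, which held 145 control cells.

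Scaling turned the sign of list medians near 0. With median-of-ratios scaling the calcium handling median turned from −0.066 to 0.021 and oxidative phosphorylation from −0.054 to 0.047 at 3 weeks against 2 weeks, and mitochondrially encoded genes from −0.12 to 0.0027 at 3 weeks against control. With mitochondrial and ribosomal genes out of the total, the 3 weeks against control medians turned from −0.14 to 0.097 for YAP targets, from −0.19 to 0.034 for BMP or TGF-beta genes and from −0.12 to 0.0088 for mitochondrially encoded genes. The smaller total also let more genes past the 50 CPM minimum (3294 against 2491 ranked). The ranked members of a list could change with it, so these turns need not be scaling alone. In total 361 of 610 list medians compared stayed the same, 235 moved and 14 turned sign, and of 791 values for named genes and Piezo1 448 stayed, 336 moved and 7 turned sign.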

Other observations

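Macrophage-like cells of the 3-week knockout, compared with control, held less of genes of alternative activation and more of immediate early genes. Of 7 alternative activation genes 0 were higher, 4 lower and 3 between, with Retnla 3.22-fold, Ccl8 2.43-fold and Folr2 2.42-fold lower (median log2 ratio −0.83, percentile 0). Of 7 MHC class II genes 1 was higher and 6 between (0.34, percentile 96.1), and 11 of 13 immediate early genes were higher and 0 lower (1.34). These values come from 110 and 108 cells, and 65 genes were at least 2-fold higher and 155 lower, the median log2 ratio of all ranked genes being −0.16. All 3 libraries expressed Xist (1549, 1312 and 1294 CPM in epithelial cells), and Ddx3y, Eif2s3y and Uty had 0 UMIs, so they look like female samples. Across genes, which are not independent replicates, log2 ratios of basal-like and dermal papilla-like cells correlated at 0.62 for 2 weeks against control, 0.47 for 3 weeks against 2 weeks and 0.70 for 3 weeks against control, so part of each difference was shared by cells outside the driver's reach.

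Of the weighings that follow, the tests on basal genes and on cell shares were chosen after the result was seen, and the test on near-identical copies was written before its value was computed.

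The first pattern is the 22 genes lower in both knockout libraries in basal-like cells, among them F3, Phlda1 and Ccdc71l. With both basal clusters weighed equally the median log2 ratio was −0.84 (−1.05 to −0.81 by resampling genes), against −1.31 in the class. A different mix of the 2 clusters alone thus did not account for the whole difference between these libraries. The genes were picked for low values in these same cells, so a median below 0 is partly built in. Equal weighing also follows the larger cluster, which most of these genes mark, and resampling genes does not measure the spread between mice. This median therefore does not decide the cause of the rest. The median was −1.06 (−1.23 to −0.97) in the larger cluster and −0.04 (−0.29 to 0.11) in the smaller, where the genes went both ways, Bst2 being lower there too (−1.29 and −2.11). The median in dermal papilla-like cells was −0.25 (−0.43 to −0.04), which decides nothing as 12 of the 22 genes had under 50 UMIs there in control. Over the other 10 it was −0.35 (−0.66 to −0.02) against −1.36 in basal-like cells. These genes were picked for low basal values, which sets the basal median further from 0 than in other classes even under a shared shift. A shift of whole libraries is therefore not decided, as the whole cause or as a part. The age of the mice could act on the 3-week values only, because the control and the 2-week knockout were of the same age. Loss of Piezo1 in basal cells might lower these genes, but a finer mix of states within the larger cluster and the single control library could do the same, and this stays open.

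The second pattern is the higher bulge share and the lower dermal and immune shares in the 2-week knockout library. An even loss of all cells outside the epithelium is argued against, because the ratios of shares to control among 9 types differed 25.0-fold, from 0.0331 (0.0130 to 0.0706) in macrophage-like to 0.828 (0.621 to 1.11) in Schwann-like cells. An even uptake of more whole hair follicles would raise the sebaceous share too. Sebaceous gland-like cells were 0.385% (0.239 to 0.588) of epithelial cells other than bulge against 3.56% (2.90 to 4.32) in control, lower in every clustering run. This argues against an even uptake of whole follicles alone. A separate loss of sebaceous cells in digestion would give the same value, so whether more follicles were taken up is not decided. The upper hair follicle-like share of those cells decided nothing: it was 20.3% against 26.1%. It was higher than in control at Leiden resolution 2 (14.1% against 12.8%) and with each library clustered on its own (8.67% against 8.17%). A loss of cells outside the epithelium that acts differently on each type during digestion may explain the lower dermal and immune shares as well as the knockout might. The 3-week fibroblast share lay near that of control. Such a loss would not change the bulge share of epithelial cells (16.1%, 35.5% and 12.4%), whose cause is not settled here. Tissue sections counted for bulge and dermal cells would be needed, and this stays open.

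The third pattern is the genes at least 1.5-fold lower at 3 weeks against 2 weeks in every class taken, among them Wdr89 and Pmepa1. The classes taken were basal, suprabasal, upper hair follicle, bulge and dermal papilla-like cells, without fibroblast-like cells. The log2 ratios were alike across them for Wdr89 (−2.40 to −2.25) but less so for Pmepa1 (−1.22 to −0.70). Reads shared with near-identical copies could produce such a difference, and 66.7% (9.43 to 99.2) of the 3 genes had a copy at the 3' end, against 27.3% of 1269 other ranked genes. With 3 genes this cannot be told apart from chance. Differences between the mice at other loci, or in sequencing, may act in the same way and were not tested, so these genes stay open.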
